A study of Mus musculus with 2 samples.

How the data were processed

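Droplet-based 3' single-cell RNA-seq of mouse immune cells was measured in 2 libraries, 1 from floxed mice without Cre (WT) and 1 from mice with hepatocyte deletion of Bicd2 (KO). The authors deposited, for each library, a matrix of raw UMI counts made with Cell Ranger, and the values are whole-number counts with no normalization. The file headers name Cell Ranger 8.0.1, while the submitters' processing notes name Cell Ranger 6.0.1, Seurat 4.3.0 and the mm39 genome. No deposited barcode held fewer than 500 UMIs. The matrices covered 33696 genes, of which 52 shared their symbol with another and were kept apart by identifier. The reference annotation at hand was of another genome build, so no coordinates are given.

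Barcodes with fewer than 200 genes (1919 WT and 9283 KO) or more than 20% mitochondrial UMIs (178 and 113) were left out. Doublets were marked with Scrublet in scanpy 1.11.5, run per library with an expected rate of 0.8% per 1000 barcodes, and the 2847 WT (14.1%) and 2215 KO (12.5%) marked barcodes were removed. This left 17320 WT cells with 66047981 UMIs and 15460 KO cells with 41674206 UMIs. Kept WT cells had a median of 2782.5 UMIs (quartiles 1565 to 4724) and 1201 genes, and kept KO cells 2009 UMIs (quartiles 1228 to 3289) and 951 genes. Haemoglobin took 15.4% of all UMIs in the WT library and 38.7% in the KO library.

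Cells of both libraries were clustered together after scaling to 10000 counts per cell and a log transform, with 2000 variable genes chosen with the library as batch key, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1 with a fixed seed, which gave 32 clusters. Immunoglobulin and T-cell receptor segments, mitochondrial, ribosomal protein, haemoglobin and sex genes were not used for clustering. Clusters were named as X-like only from cell type markers fixed before the data were examined, as were the gene lists, the rule for named genes and the intervals and list medians used in the report. The tests of explanations in the closing section were chosen later. The naming thresholds were set later: a marker counted when at least 2-fold higher than in other cells and seen in at least 10% of the cluster's cells, at least 3 markers were needed, and a cluster whose 10 leading genes held more markers of another type stayed unnamed. Clusters with a median haemoglobin share above 10% stayed unnamed unless erythroid, and erythroid-like clusters needed 75%. Lineage names were rebuilt here and are not those of the study.

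With 1 library per group no test across samples exists, and no p-value, standard error or count of changed genes is given. Shares of cells carry exact Clopper-Pearson intervals, and ratios of shares a log-normal counting interval. UMIs were summed per library and lineage for the 8 lineages with at least 100 cells in each library and for all kept cells, and scaled to CPM. Sums carry exact Poisson intervals and ratios of sums exact conditional binomial intervals. Log2 ratios are KO over WT of CPM plus 1. For each of 25 fixed gene lists, 17 of them primary, the median log2 ratio of members with a summed count of at least 20 was placed among 10000 random lists of the same size drawn from the same 20 expression bins, and a list was said to stand apart in the outer 2.5% on either side. Named genes were the 10 highest and 10 lowest log2 ratios per lineage among genes with at least 50 counts, 50 CPM and a UMI in 5% of cells in the higher library, and a counting interval that left out equality. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, T-cell receptor, predicted and sex genes and markers of other lineages were not eligible, and members of the fixed lists and markers could also be named. Shares of cells with a UMI were taken after thinning every cell to 1000 UMIs, which left out 1952 WT and 2612 KO cells. For a count of 0 the limit allowed is that of 3 counts.

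The alternatives tried were edgeR 4.0.16 TMM and DESeq2 1.42.0 scaling, no minimum count or 100 for lists, pseudocounts of 0.1 and 10, at least 500 genes with at most 10% mitochondrial UMIs, doublets kept, genes centred within each library and thinned cells. Further alternatives were chosen after seeing the data: leaving out cells over 10% haemoglobin or haemoglobin genes, a total without red-cell clusters, subtraction of estimated free RNA, and the genes Zbtb16, Ifng, Gzmb and 1 more, not reported here, for shares of cells. Free RNA was estimated from the neutrophil genes S100a8 and S100a9 in B-like cells, with the mean of all barcodes as its profile, at 167 UMIs per cell in WT and 102 in KO. The interval and list procedures were tested on simulated Poisson sums with changes planted in 200 genes per lineage. The intervals held the true ratio in 95.7% to 96.4% of all genes tested, most of them unchanged, across lineages. Such sums follow the counting model of the intervals, so they cannot show how the intervals hold where UMIs of a gene come from few cells. Of simulated lists without a planted change 0% to 10% stood apart, depending on the lineage, against 5% by design. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and R 4.3.3, were used.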

Results

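Bicd2, which encodes an adaptor that couples cargo to the dynein motor, was the targeted gene. Mice with floxed Bicd2 alleles and no Cre (WT) were compared with mice carrying Cre under the albumin promoter, which deletes the gene in hepatocytes (KO). Per the series text, the mice were given 2.5 mg of S-100, a liver homogenate supernatant in complete Freund's adjuvant, into the peritoneum every week for 3 weeks, which models autoimmune hepatitis. The text says that liver immune cells were enriched on a Percoll gradient, freed of red cells by lysis, sorted alive and pooled. The sample labels instead call the cells peritoneal and carry the treatment tag HFD, and this conflict was not resolved by the labels. Each genotype was measured in 1 single-cell RNA library, so no difference given here has a replicate check, and all intervals are 95% intervals that cover counting error only. The WT library held 22197 barcodes with 81159013 UMIs and the KO library 27033 barcodes with 63869430 UMIs. After filtering, 17320 WT cells (median 2782.5 UMIs) and 15460 KO cells (median 2009 UMIs) were kept.

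Bicd2 was counted 1310 times in the kept WT cells (Poisson interval 1240 to 1383) and 553 times in the kept KO cells (508 to 601). This was 19.8 and 13.3 UMIs per 1000000 UMIs of the cells concerned (CPM), a KO level 0.669 times that of WT (interval 0.605 to 0.7395). In T-like cells it was 25.9 CPM in WT and 16.8 CPM in KO. These are immune cells, in which the albumin-driven Cre is not expected to act, so the values do not measure the deletion. In cluster 26, which carried hepatocyte transcripts such as Alb, Bicd2 had 0 of 109715 UMIs in WT, which allows up to 27.3 CPM, and 3 of 285866 UMIs in KO.

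The comparison of KO with WT asks how these immune cells differ when hepatocytes lack Bicd2. Neutrophil-like cells made up 25.03% of kept WT cells (exact binomial interval 24.4 to 25.7) and 9.74% of kept KO cells (9.28 to 10.2), a share 2.57-fold lower in KO (2.43 to 2.71). B-like cells went the other way, at 4.17% (3.88 to 4.48) and 9.66% (9.202 to 10.1), a share 2.32-fold higher in KO (2.13 to 2.53). Progenitor-like cells, marked by early myeloid genes such as Mpo, Elane and Prtn3, numbered 533 in WT and 52 in KO, 3.08% against 0.336%. T-like cells were near a similar share, at 31.9% and 31.3%, a log2 ratio of -0.03 (interval -0.07 to 0.02).

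Plasmacytoid dendritic (pDC-like) cells, the main producers of type I interferon, were at 1.15% in WT and 1.89% in KO, a log2 ratio of 0.72 (interval 0.46 to 0.98). Conventional dendritic (DC-like) cells were at 3.77% and 4.38%, a log2 ratio of 0.22 (interval 0.06 to 0.37). Monocyte-macrophage-like cells were at 9.99% and 11.2%, a log2 ratio of 0.16 (interval 0.07 to 0.25). Cells resembling natural killer cells and type 1 innate lymphoid cells (NK-ILC1-like) were at 9.56% and 8.64%, a log2 ratio of -0.15 (interval -0.25 to -0.05). Plasma-like cells, which secrete antibody, numbered 66 and 35, a log2 ratio of -0.75 (interval -1.34 to -0.16), or -0.55 (interval -1.14 to 0.04) on the total without red-cell clusters described below. Erythroid-like cells formed 8.68% of kept cells in WT and 6.07% in KO. This does not show fewer red cells in KO, since the minimum of genes per cell left out many barcodes with much haemoglobin. Before filtering, barcodes with more than 50% haemoglobin UMIs made up 16.6% of WT and 44.5% of KO barcodes. The median number of genes of such barcodes was 199 in WT and 149 in KO. Clusters with much haemoglobin that stayed unnamed formed 2.31% of kept WT cells and 16.6% of kept KO cells. One of these unnamed clusters carried B markers and held 33 WT and 547 KO cells, 1 carried hepatocyte transcripts and 4 carried red-cell genes. Because red-cell lysis, the sort and the depth can set such shares, they were also taken without erythroid-like and haemoglobin-high clusters. Neutrophil-like cells were then 28.1% and 12.6%, B-like cells 4.68% and 12.5%, T-like cells 35.8% and 40.5%, monocyte-macrophage-like cells 11.2% and 14.5% and DC-like cells 4.24% and 5.66%. The NK-ILC1-like log2 ratio turned to 0.06 on that total, and the DC-like one turned to -0.22 when cells over 10% haemoglobin were left out before clustering. The monocyte-macrophage-like log2 ratio was 1.12 and the DC-like one 0.60 with genes centred within each library, the pDC-like one was 0.41 and the T-like one 0.31 with cells over 10% haemoglobin left out, and the neutrophil-like one was -2.11 with cells thinned to 1000 UMIs. With centring, a cluster of 929 WT and 71 KO cells that met classical monocyte markers stayed unnamed, so the 1.12 leaves those cells out. Centring also left some cell types split by library. Large T-like clusters held 18 WT and 3196 KO, and 3164 WT and 18 KO cells. B-like clusters held 12 WT and 1314 KO, and 701 WT and 2 KO cells. The largest DC-like cluster, with 379 WT and 691 KO cells, had the monocyte-macrophage marker C1qb among its leading genes. The 0.60 may therefore count some cells that are not dendritic.

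**Figure D1:**
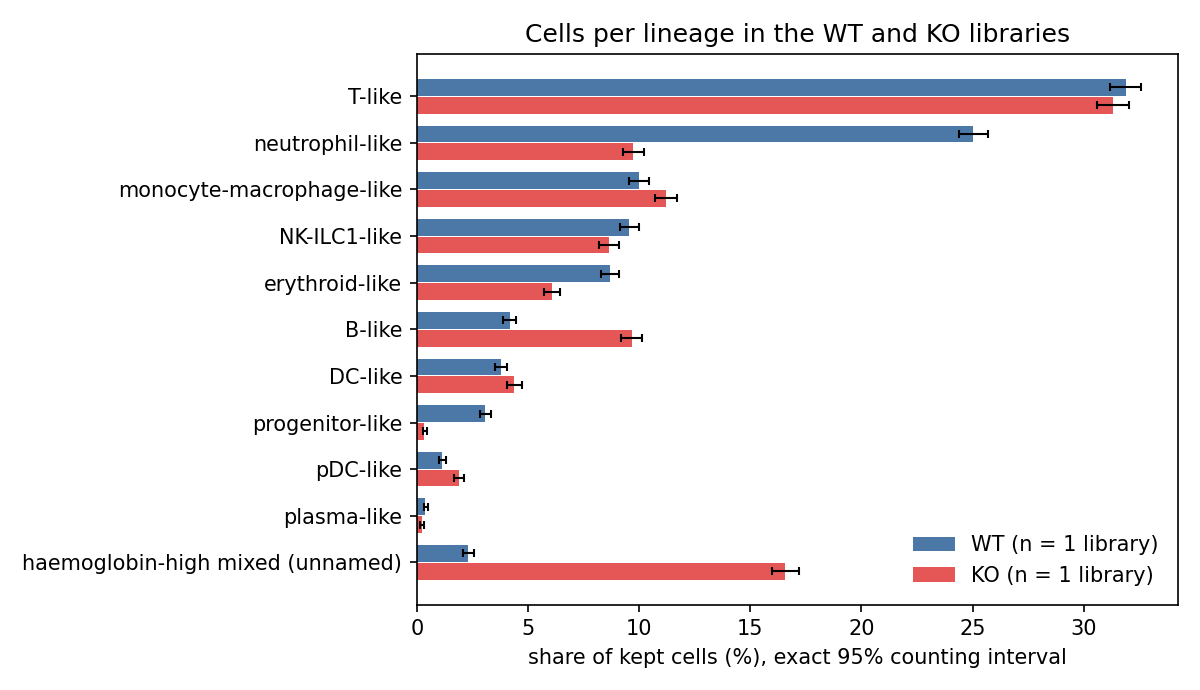
Share of kept cells per lineage (%, linear axis) in the WT and KO libraries, with exact binomial 95% intervals as bars. The neutrophil-like share was 25.03% in WT and 9.74% in KO, and the B-like share 4.17% and 9.66%.

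Genes induced by interferon-gamma, the cytokine by which T and NK cells activate macrophages, were lower in KO in each of the 7 leukocyte lineages compared. The median log2 ratio of this list was -2.23 in monocyte-macrophage-like, -1.62 in DC-like, -1.497 in neutrophil-like, -1.37 in B-like, -1.37 in pDC-like, -1.35 in NK-ILC1-like and -1.09 in T-like cells. Each of these lay below all 10000 random lists matched on expression, a description of these libraries and not a test. Of the measured members, 19 were lower and 0 higher in monocyte-macrophage-like cells, 18 and 0 in B-like cells, and 18 and 1 in T-like cells. Genes of MHC class I presentation, by which cells show peptides to CD8 T cells, were lower alongside: all 18 members were lower in each of the 7 lineages, with medians from -1.35 in monocyte-macrophage-like to -0.65 in T-like cells. Both lists were lower in erythroid-like cells too, with medians of -1.40 for interferon-gamma and -0.99 for MHC class I. Ifng itself, the gene of the cytokine, was 6.98-fold (interval 5.802 to 8.46) lower in T-like cells (80.8 CPM in WT and 11.6 in KO) and 4.19-fold lower in NK-ILC1-like cells. Most WT T-like cells lay in cluster 2 and most KO ones in cluster 0, and within these clusters the difference in Ifng was smaller, at 113 and 31.6 CPM in WT and KO in cluster 2 (3119 and 74 cells) and 33.5 and 16.1 in cluster 0. Within 19 single clusters with at least 50 cells per library, a comparison chosen after seeing the data, the interferon-gamma list stood apart lower in 19 and MHC class I presentation in 19.

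Genes induced by type I interferon, the antiviral cytokines, differed less. Their median was -0.78 in monocyte-macrophage-like, -0.66 in neutrophil-like, -0.53 in NK-ILC1-like and -0.39 in B-like cells, all at or below percentile 2.5 of the random lists. The type I interferon response in B-like cells no longer stood apart with cells over 10% haemoglobin left out (-0.15) or cells thinned (-0.27). In DC-like cells it was -0.09 (percentile 59.9), in T-like cells -0.20 (percentile 13.4) and in pDC-like cells -0.45 (percentile 2.99). The list did stand apart with cells over 10% haemoglobin left out in DC-like (-0.22) and pDC-like cells (-0.39), and in pDC-like cells also when thinned (-0.67). Within single clusters it stood apart lower in 8 of 19, was 0.06 in neutrophil-like cluster 6 and stood apart higher in T-like cluster 2 (0.69, percentile 99.9). Rsad2, an antiviral member, was 3.52-fold higher in KO DC-like cells. Cell-cycle genes were lower in KO in all 7 lineages, with medians from -2.01 in neutrophil-like and -1.95 in T-like cells, where all 20 members were lower, through -1.09 in NK-ILC1-like, -1.01 in B-like, -0.89 in monocyte-macrophage-like and -0.82 in pDC-like to -0.39 in DC-like cells. The cell cycle list no longer stood apart in NK-ILC1-like cells with a minimum count of 100 (-0.44) or thinned cells (-0.36), in DC-like cells with cells over 10% haemoglobin left out (-0.0825), and in pDC-like cells with free RNA subtracted (-0.54). Within single clusters it stood apart lower in 12 of 19, and not in T-like clusters 12, 13 and 14 (-0.24, -0.18 and -0.19). Other scalings (TMM and DESeq2) moved the median log2 ratio of all genes by over 0.1 in 3 lineages, by 0.11 and 0.10 in DC-like, 0.18 and 0.18 in NK-ILC1-like, and 0.19 and 0.20 in pDC-like cells, and list percentiles are relative to such shifts.

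**Figure D2:**
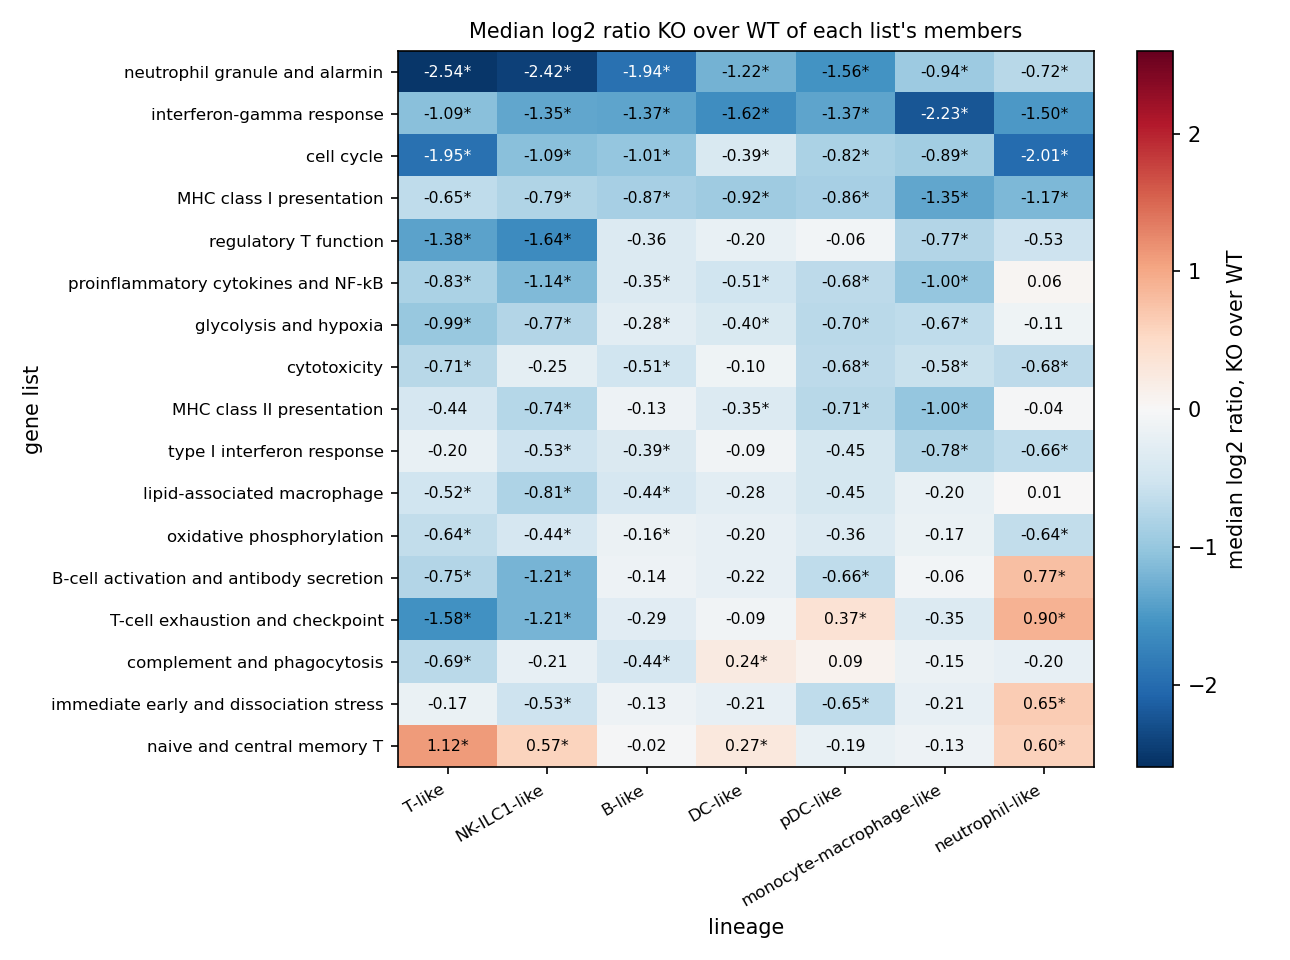
Median log2 ratio (KO over WT) of each gene list, listed on the vertical axis, in each lineage on the horizontal axis, as colours, with a star where the median lay in the outer 2.5% of 10000 random lists on either side. The interferon-gamma list ran from -2.23 in monocyte-macrophage-like to -1.09 in T-like cells.

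In monocyte-macrophage-like cells the genes lowest in KO included many targets of interferon-gamma. Iigp1, a GTPase that attacks vacuoles of intracellular pathogens, was 27.7-fold (interval 22.7 to 34.1) lower (389 CPM in WT and 14.04 in KO). Cxcl10 and Cxcl9, chemokines that draw activated T cells, were 19.7-fold (interval 17.1 to 22.7) and 12.7-fold lower. The guanylate-binding proteins Gbp6 and Gbp2 were 16.4-fold and 10.1-fold lower, Ly6a and Ly6i, surface proteins of the Ly6 family, 11.98-fold and 11.2-fold, the serine protease inhibitor Serpina3g 11.7-fold, the noncoding transcript AW112010 11.9-fold and the uridine phosphorylase Upp1 19.5-fold. Of 11 genes of MHC class II presentation, by which peptides are shown to CD4 T cells, 10 were lower and 1 higher (median -0.997): H2-Aa was 2.16-fold, Cd74 2.13-fold and the class II regulator Ciita 2.01-fold lower, while the lysosomal protease Lgmn was 1.47-fold higher. Among proinflammatory and NF-kB genes 14 of 18 were lower (median -1.004), with the cytokine gene Tnf 3.89-fold, the NF-kB inhibitor Tnfaip3 5.35-fold and Il1b 1.98-fold lower. Of the chemokines and receptors 17 were lower and 4 higher (median -1.28): Ccl5 was 9.21-fold lower and the receptor Cxcr4 2.68-fold higher. Glycolysis genes had a median of -0.67, with all 18 members lower.

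Higher in KO monocyte-macrophage-like cells were Adgrl3, an adhesion receptor, by 8.38-fold (interval 7.03 to 10.1), Thbs1, the matrix protein thrombospondin, by 7.98-fold, Setbp1 by 5.53-fold, the TGF-beta co-receptor Tgfbr3 by 4.76-fold and the fatty-acid carrier Fabp4 by 3.69-fold. Complement and phagocytosis genes (median -0.15, percentile 21.3) and genes of lipid-associated macrophages (median -0.20, percentile 12.8) did not stand apart from random lists, but in thinned cells both did, at -0.44 and -0.51. In these values WT cells came from cluster 7 (588 cells), cluster 8 (838) and cluster 11 (304), and KO cells from the same clusters with 671, 357 and 701 cells. Clusters 7 and 8 carried markers of classical monocytes and cluster 11 of nonclassical monocytes.

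In KO, T-like cells carried less of the effector cytokine Il21 (70.3-fold (interval 19.3 to 583)), the macrophage growth factor Csf1 (41.4-fold (interval 30.1 to 58.7)), the chemokine Ccl4 (13.6-fold), the costimulatory receptor Tnfrsf4, also called OX40 (10.6-fold), and the proprotein convertase Furin (8.77-fold). When T-like cells were clustered again, Il21 was among the leading genes of a sub-cluster of 28 WT and 0 KO cells. Its UMIs may thus come from few cells, where the interval was not shown to hold. Also 19.2-fold and 21.6-fold lower were Arnt2, a transcription factor of the bHLH-PAS family, and Or13a27, annotated as an olfactory receptor. The fatty-acid carrier Fabp5 was 10.7-fold lower, and the inhibitory receptors Lilrb4a and Lilrb4b 7.59-fold and 8.18-fold. In the same re-clustering, Or13a27, Arnt2, Lilrb4a, Lilrb4b, Csf1 and Furin led a sub-cluster of 1948 WT and 11 KO cells. Their lower values may thus follow in part from fewer such cells in KO. KO T-like cells carried more Il4, a type 2 helper cytokine (11.02-fold, 6.17 to 67.96 CPM), Zbtb16, which encodes PLZF, a transcription factor of innate-like T cells (6.66-fold, 56.2 to 374 CPM), and the zinc-finger gene Glis3 (10.5-fold). Within cluster 0 alone the differences were smaller, with Il4 at 59.5 and 108 CPM and Zbtb16 at 451 and 574 CPM in WT and KO. Higher too were the potassium channel Kcnq5 (5.85-fold), the water channel Aqp9 (7.15-fold), the phosphodiesterase Pde2a (4.57-fold) and the lysosomal trafficking gene Lyst (4.28-fold).

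Of the 12 exhaustion and checkpoint genes in T-like cells, 9 were lower and 3 higher (median -1.58): the inhibitory receptors Ctla4, Tigit, Lag3 and Pdcd1 were 4.94-fold, 4.86-fold, 4.51-fold and 3.11-fold lower. All 10 genes of naive and central memory T cells were higher (median 1.12, above all random lists), with the lymph-node homing receptor Ccr7 3.53-fold, the transcription factor Lef1 2.71-fold and the chromatin organiser Satb1 2.61-fold higher. Of the cytotoxicity genes 11 were lower and 4 higher (median -0.71), the granzymes Gzmk and Gzma by 7.24-fold and 7.08-fold, and the killer-cell receptor subunit Klrd1 was 1.92-fold higher. When T-like cells were clustered again, sub-clusters 10 and 12, with Gzma among their leading genes and natural killer cell genes beside it in the first, held 148 and 118 WT but 7 and 4 KO cells. Genes of regulatory T cells were lower in 9 of 12 cases (median -1.38), with their master regulator Foxp3 3.93-fold lower. The list of helper T cytokines and regulators was mixed, with 6 higher and 7 lower (median -0.42, percentile 2.33), and their median turned to 0.11 with no minimum count and no longer stood apart with a minimum of 100 (-0.0452) or in thinned cells (-0.0839). The medians of glycolysis and hypoxia (-0.99), oxidative phosphorylation (-0.64), proinflammatory (-0.83) and chemokine genes (-0.92) were below all random lists, and Gapdh, a glycolytic enzyme, was 4.15-fold lower. Most WT T-like cells lay in cluster 2 (56.5%) and most KO T-like cells in cluster 0 (65.1%), so these values compare T-like populations with a different makeup.

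Shares of T-like cells with at least 1 UMI of a gene were taken after thinning every cell to 1000 UMIs, since the median depth of T-like cells was 2661 and 1839 UMIs in WT and KO. 772 WT and 874 KO T-like cells below that depth were left out. B-like cells, with median depths of 2152.5 and 1558, gave the background from free RNA. Cd4, the coreceptor of helper T cells, was seen in 27.3% and 9.33% of WT and KO T-like cells (background 1.32% and 0.519%, unthinned 50.1% and 15.95%). Mki67, a marker of dividing cells, was seen in 14.1% and 3.03% (background 1.48% and 0.433%, unthinned 22.96% and 4.15%). Zbtb16 was seen in 4.63% and 26.2% (background 0.165% and 0.865%, unthinned 8.22% and 38.4%). Ifng was seen in 5.999% and 0.933% (unthinned 14.6% and 2.09%), with a background of 0.494% in WT and 0 of 1156 cells in KO, which allows a share of up to 0.2595%. Pdcd1 was seen in 2.15% and 0.454% (unthinned 6.55% and 1.24%), with 0 of 607 WT and 0 of 1156 KO B-like cells, which allows up to 0.494% and 0.2595%. Foxp3 was seen in 1.64% and 0.5295% (background 0.329% and 0.0865%, unthinned 3.49% and 0.826%). Cd8a, the coreceptor of cytotoxic T cells, was close, at 2.72% and 3.15% (background 0.824% and 0.173%, unthinned 5.65% and 6.302%), as was granzyme Gzmb at 8.78% and 8.396% (background 1.48% and 0.433%, unthinned 16.7% and 12.6%). Clustering the T-like cells again gave a regulatory T-like share of 6.03% in WT (5.42 to 6.69) and 3.905% in KO (3.38 to 4.49). A sub-cluster that met the CD4 T-like markers, though led by activation genes such as Il21 and Ccl4, held 28 WT cells (0.507%) and 0 of 4840 KO cells, which allows a share of up to 0.06198%. It is not a share of all CD4 T cells: sub-clusters 0 and 2, which stayed unnamed with Cd4 among their leading genes, though in sub-cluster 2 behind neutrophil transcripts such as Camp and S100a9, held 1948 and 1058 WT and 11 and 4 KO cells. The other 93.5% and 96.1% stayed unnamed.

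**Figure D3:**
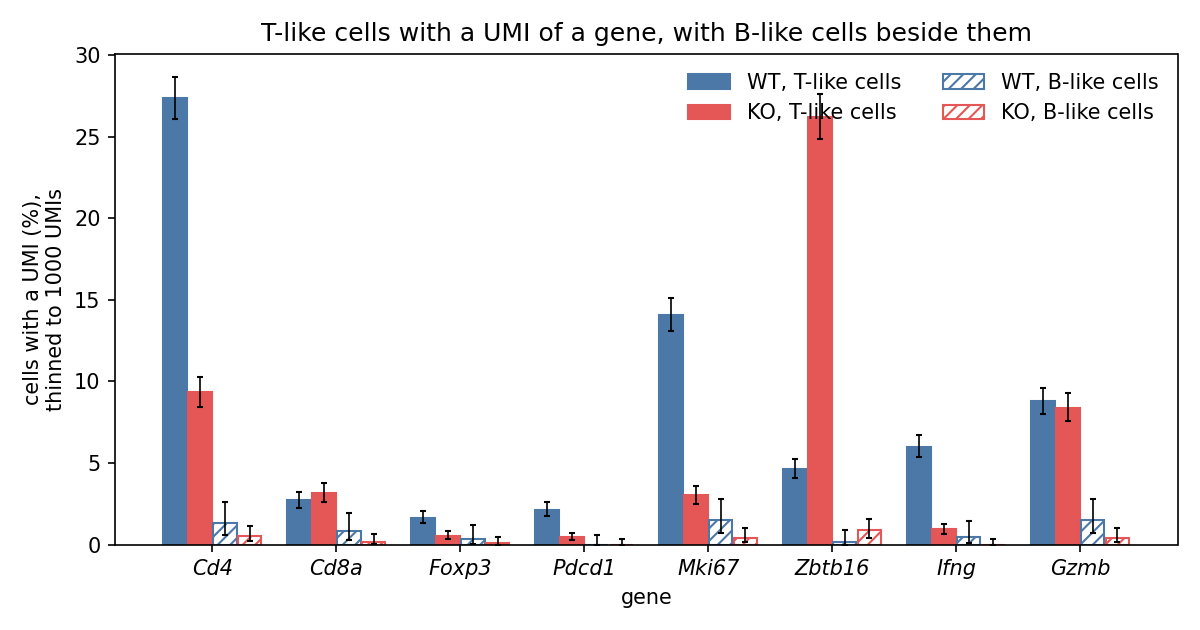
Share of T-like cells with a UMI of each gene (%) in the WT and KO libraries after thinning to 1000 UMIs per cell, with B-like cells as background and exact binomial 95% intervals as bars. Zbtb16 was at 4.63% and 26.2% and Cd4 at 27.3% and 9.33% of WT and KO T-like cells.

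NK-ILC1-like cells carried less checkpoint RNA in KO, but all 10 measured genes of regulatory T cells were lower in this lineage too. T-cell transcripts were more frequent in its WT cells. Trac had a UMI in 28.3% of WT and 8.39% of KO cells, and Cd8a in 10.98% and 3.52% after thinning. The values of this lineage therefore compare cells with a different makeup. Gzmc, a granzyme of strongly stimulated killer cells, was 13.3-fold lower, Xcl1, a chemokine that attracts dendritic cells, 4.98-fold (1206 to 242 CPM), Furin 4.86-fold and the cell-division enzyme Top2a 5.8-fold. The adhesion molecules Dscam and Jaml were 9.03-fold and 5.35-fold lower and the semaphorin Sema6d 6.28-fold. Higher in KO were Angpt1, a ligand of the endothelial receptor Tie2, by 18.7-fold (interval 12.4 to 29.6), and the sortilin-family receptor Sorcs2 by 5.98-fold. Of the exhaustion and checkpoint genes 10 of 12 were lower (median -1.21), Lag3 by 3.17-fold, and the proinflammatory median was -1.14. Medians were -0.87 for chemokines and receptors, -0.77 for glycolysis and hypoxia and -0.44 for oxidative phosphorylation, the last no longer apart in thinned cells (-0.26). The naive and central memory list was higher (median 0.57). Cytotoxicity genes did not stand apart (median -0.25, percentile 41.1): Gzmb was 2.03-fold lower, while Gzma was 1.31-fold and the maturation factor Zeb2 2.55-fold higher. WT cells lay in clusters 5 (904), 21 (463) and 10 (289), and KO cells mostly in clusters 10 (872) and 5 (439), with 24 in cluster 21.

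Neutrophil-like cells in KO carried less RNA of granule proteins made early in maturation and of cell division, and, at full depth, more of immediate early genes. Elane, the elastase of primary granules, was 39.4-fold lower, and Camp, Ngp and Ltf, proteins of secondary granules, were 4.302-fold, 3.45-fold and 2.87-fold lower. Of the granule and alarmin genes 17 of 20 were lower (median -0.72), and the alarmin-family gene S100a6 was 1.09-fold higher. The lectin Fcnb was 6.46-fold lower, the microtubule regulator Stmn1 6.77-fold, and Cdca8, Cenpf and Birc5, which act in chromosome segregation, 6.54-fold, 5.58-fold and 4.74-fold. The interferon-induced GTPase Igtp was 5.37-fold lower, and the MHC class I genes H2-Q7 and H2-Q6 5.55-fold and 4.99-fold. Of the immediate early genes 16 were higher and 2 lower (median 0.65, percentile 99.8), with the transcription factors Jund, Junb and Fos 2.78-fold, 2.37-fold and 1.82-fold higher. In thinned cells that median was 0.38 and no longer stood apart. The phosphodiesterase Pde7b was 4.44-fold higher, the magnesium transporter gene Cnnm2 7.45-fold, the ubiquitin ligase Rnf125 5.92-fold and the hormone gene Retn 4.48-fold. The proinflammatory list did not stand apart (median 0.06), and the oxidative phosphorylation median was -0.64. Cluster 1 held 51.1% of WT and 85.6% of KO neutrophil-like cells, clusters 6, 18 and 23 held 1220, 452 and 446 WT and 121, 81 and 15 KO cells, and median depth was 2153 and 1023.5 UMIs. Camp, Ngp and Ltf led clusters 6 and 23, so the lower granule RNA may follow in part from fewer such cells in KO.

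B-like cells in KO carried less RNA of interferon targets, with Iigp1 67.7-fold (interval 22.6 to 333), the protease inhibitors Serpina3f and Serpina3g 8.02-fold and 6.54-fold and Gbp2 5.77-fold lower. The interleukin-9 receptor Il9r was 3.43-fold lower. Higher were the phosphodiesterase Pde3b by 2.41-fold, the carboxypeptidase gene Agbl1 by 2.31-fold and the transcription factor Sox5 by 2.24-fold. The lists of B-cell activation and antibody secretion (median -0.14, percentile 12.4, 6 higher and 10 lower) and of MHC class II presentation (median -0.13, percentile 8.12) did not stand apart. B-cell activation and antibody secretion did stand apart lower with cells over 10% haemoglobin left out (-0.53) and with the stricter cell filter (-0.63). In this list, the immunoglobulin gene Ighg2b was 5.08-fold higher and the death receptor Fas 4.96-fold lower.

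In DC-like cells Iigp1, Cxcl10, Cxcl9 and Gbp5 were 25.7-fold, 14.5-fold, 8.098-fold and 8.06-fold lower in KO, the granzyme inhibitor Serpinb9 4.51-fold and Ly6a 5.902-fold. Of the MHC class II genes 10 of 11 were lower (median -0.35, percentile 2.1), and medians were -0.51 for proinflammatory and -0.40 for glycolysis genes. The MHC class II presentation list no longer stood apart with a minimum count of 100 (-0.35), the stricter filter (-0.33) or thinned cells (-0.27), nor did glycolysis and hypoxia in thinned cells (-0.32). Cluster 29, which carried markers of migratory dendritic cells, held 13.02% of WT and 3.55% of KO DC-like cells (85 and 24 cells), so the makeup differed here too. Adgrl3 was 4.23-fold higher, as in monocyte-macrophage-like cells, and the FERM-domain gene Frmd5 5.56-fold higher. In pDC-like cells Iigp1 was 13.3-fold, Ly6a 3.51-fold and the Ly6-family gene Ly6k 7.02-fold lower, and the B-cell scaffold gene Bank1 was 26.3-fold higher, where the B marker Cd79a was at 2.59 and 36.3 CPM in WT and KO. The pDC-like medians were -0.71 for MHC class II and -0.70 for glycolysis and hypoxia.

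Over all kept cells most of the genes lowest in KO were genes of neutrophil-like and progenitor-like cells, whose shares were lower: Elane was 124-fold, the granule protease Prtn3 22.9-fold, Camp 17.7-fold, Ngp 14.3-fold, the neutrophil surface marker Ly6g 13.8-fold and the iron-binding Lcn2 9.91-fold lower. Cxcl10 and Cxcl9 were 13.02-fold and 9.53-fold lower. Zbtb16 was 5.15-fold, the cytokine-signal inhibitor Socs2 4.25-fold, the B-cell gene Ms4a1 (CD20) 3.28-fold and Ace, which marks nonclassical monocytes, 3.09-fold higher. In erythroid-like cells the stress transcription factor Atf5 was 14.6-fold and the apolipoprotein L genes Apol11a and Apol11b 10.4-fold and 4.46-fold lower, while the poly(A)-binding protein Pabpc1 was 2.54-fold and the Mediator kinase Cdk8 2.39-fold higher. Red-cell genes were also higher in KO leukocytes, where haemoglobin RNA was more abundant: Hbb-bs was 6533 and 15287 CPM in WT and KO B-like cells. The red-cell gene Tent5c had a log2 ratio of 2.63 in NK-ILC1-like and 1.596 in B-like cells, and 1.33 and 0.16 with cells over 10% haemoglobin left out. Free RNA of neutrophils was higher in WT, with S100a8, an alarmin that B cells lack, at 1512 and 155 CPM in WT and KO B-like cells. The granule list was lower in KO outside neutrophils too. Its medians were -1.94 in B-like cells (-0.66 with free RNA subtracted) and -2.54 in T-like cells. The subtraction was set from S100a8 and S100a9 in B-like cells, and both are members of this list. The -0.66 is therefore no independent measure of how much was free RNA.

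Because the labels name both the liver and the peritoneum, marker genes of each were measured. In monocyte-macrophage-like cells Clec4f, a marker of Kupffer cells, the liver's resident macrophages, was at 21.5 and 2.78 CPM in WT and KO, Marco at 21.9 and 0.556, Cd5l at 61.97 and 21.7 and Timd4 at 6.27 and 0.278, while C1qa was at 131 and 148 CPM. Of genes fixed beforehand as markers of peritoneal macrophages, Gata6 had a UMI in 1 of 1730 WT and 6 of 1729 KO cells. Prg4 was at 15.2 and 72.03 CPM, from 6 and 17 cells, and Alox15 at 3.62 and 35.7 CPM, from 3 and 13 cells. Saa3 was at 464 and 287 CPM (375 and 129 cells) and Lyz1 at 70.4 and 15.02 CPM (80 and 31 cells). Saa3 was also among the leading genes of cluster 8, which carried markers of classical monocytes. Over all kept cells the hepatocyte gene Alb was at 5.07 and 15.96 CPM, Stab2 of liver endothelium at 0.5905 and 1.42 CPM, and Msln of mesothelium, the lining of the peritoneum, at 0.469 and 0.04799 CPM. In cluster 26, which carried hepatocyte transcripts, Alb was at 1723 CPM in 47 WT cells and 1543 CPM in 104 KO cells.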

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

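All tests below were chosen after the patterns were seen, and of their values only that on neutrophils lost to the gene minimum was still unseen when that test was fixed. Interferon-gamma response genes were lower in KO in all 7 leukocyte lineages. Free RNA from other cells as the whole cause is argued against by the highest of the 7 medians after subtraction, -0.89. The list was also lower in erythroid-like cells (median -1.40, 16 of 17 members). A part played by free RNA therefore stays open. In thinned cells the highest median was -0.97, with the list still apart in all 7. These ratios are scaled to CPM, and random thinning hardly changes proportions, so it cannot decide on the lower depth of the KO library. A shift between cell types within lineages as the whole cause is argued against by single clusters: among 19 clusters with at least 50 cells per library the list stood apart lower in 19, with medians from -2.33 to -0.33, but the medians in T-like clusters 0, 2 and 13 (-0.64, -0.33 and -0.55) and NK-ILC1-like clusters 5 and 10 (-0.84 and -0.88) were closer to 0 than those of their lineages (-1.09 and -1.35), so a part played by such a shift stays open there. With 1 library per group, an effect of Bicd2 loss in hepatocytes cannot be told apart from other differences between mice or between library preparations. Since Ifng was lower in T-like and NK-ILC1-like cells too, less interferon-gamma from these cells in the KO mice is a candidate explanation that was not tested.

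T-like cells with a Zbtb16 UMI made up 2.62% of kept cells in WT and 12.01% in KO. Free RNA is argued against by the share of thinned KO B-like cells with a Zbtb16 UMI, 0.865%, far below the 26.2% of T-like cells. A loss of other cells alone would raise every remaining type alike. The log2 ratio was instead 2.196 (interval 2.05 to 2.34), above the upper bound of 1.34 for B-like cells. The B-like value leaves out an unnamed haemoglobin-high cluster with B markers, of 33 WT and 547 KO cells, and the comparison was not repeated with it. Trav11 and Trav11d, the alpha segments of invariant natural killer T cells, gave 52.8% of T-cell receptor alpha variable UMIs in cluster 0 (interval 42.9 to 62.6) against 0.469% in cluster 2 (up to 2.59), so the Zbtb16-rich cells of cluster 0 may be invariant natural killer T cells. Whether their larger share goes with the genotype, with the mice or with the preparation stays open.

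The neutrophil-like share was lower in KO, at a log2 ratio of -1.36 (interval -1.44 to -1.28). More red cells among the KO cells are argued against as the whole cause by the ratio without erythroid-like and haemoglobin-high clusters, -1.16 (interval -1.24 to -1.08). Loss of KO neutrophils to the gene minimum cannot be told apart from fewer neutrophils in KO: counting as neutrophils the 2637 of 9283 removed KO barcodes with at least 0.413% S100a8 and S100a9 among UMIs other than haemoglobin, a level 99% of kept KO neutrophil-like cells reach, with no WT barcode added, gave -0.13 (-0.18 to -0.08), but 1846 of 1919 removed WT barcodes reached that level too, so it does not separate neutrophils from free RNA. Shallow KO neutrophils below 500 UMIs, the lowest in the matrices, may be missing: the ratio was -1.69 with the stricter cell filter and -2.11 in thinned cells, and median depths were 2153 and 1023.5 UMIs. Differences in sorting, in the density gradient or in blood and marrow cells carried along, and an effect of the genotype, stay open and untested.

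Barcodes under the gene minimum made up 34.3% of KO barcodes, above the 8.65% of the WT control, and their median haemoglobin share was 86.6% and 90.1%. Unnamed clusters with much haemoglobin held 16.6% of kept KO cells and 2.31% of kept WT cells. Some list medians were higher in KO in one lineage and lower in others, and these differences between lineages were not tested. B-cell activation and antibody secretion genes had a median of 0.77 in neutrophil-like cells, while the list was lower in NK-ILC1-like, T-like and pDC-like cells, but the neutrophil-like value turned to -0.21 in thinned cells and was 0.19, not apart, with free RNA subtracted. T-cell exhaustion and checkpoint genes had medians of 0.90 in neutrophil-like and 0.37 in pDC-like cells, against lower values in NK-ILC1-like and T-like cells, and no longer stood apart with no minimum count (0.26 and 0.13) or, in thinned neutrophil-like cells, at 0.47. Genes of complement and phagocytosis had a median of 0.24 in DC-like cells and were lower in B-like and T-like cells, but the DC-like value turned to -0.24 with cells over 10% haemoglobin left out and -0.00468 in thinned cells. Immediate early genes had a median of 0.65 in neutrophil-like cells and were lower in NK-ILC1-like and pDC-like cells, but the neutrophil-like value was 0.38, not apart, in thinned cells.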

How the results depend on the processing

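Settings that left out cells over 10% haemoglobin, haemoglobin genes or red-cell clusters or subtracted free RNA were chosen after the results were seen. So were the 86 list medians reported in the text for the 7 leukocyte lineages. The other alternatives were chosen earlier. The interferon-gamma response list kept its direction and stood apart in all 7 leukocyte lineages under each of its alternatives, with medians from -2.32 to -0.89, as did MHC class I presentation, from -1.42 to -0.54. The share log2 ratios ran from -2.11 to -1.01 for neutrophil-like and 1.05 to 1.46 for B-like cells. Of 774 values of reported list medians 737 kept direction and side, 22 no longer stood apart, 11 newly did and 4 reversed. For 88 medians not reported, 682 of 781 values kept both and 11 reversed. Of 48 values of lineage shares 25 stayed within the counting interval, 21 moved and 2 reversed, and of 1060 values of named genes 816, 240 and 4. Of 8 shares of T-like cells with a UMI 6 stayed and 2 moved without thinning. Plasma-like cells gave a value only on the total without red-cell clusters, and progenitor-like cells none in thinned cells. Depth limits low counts, and 1 library per group leaves the spread between mice unknown. Named genes moved most with a pseudocount of 10 (112 values), cells over 10% haemoglobin left out (61), DESeq2 (23) or TMM scaling (21) and free RNA subtracted (23). Shares and list medians that moved, reversed or changed side and genes that reversed follow, and the cause was not tested. With DESeq2 scaling, the list median of type I interferon response in pDC-like cells was -0.26. With TMM scaling, the list median of type I interferon response in pDC-like cells was -0.26. With haemoglobin genes left out of totals, the list median of type I interferon response in pDC-like cells was -0.24. With cells over 10% haemoglobin left out, share log2 ratios were T-like 0.31, B-like 1.46, neutrophil-like -1.01, DC-like -0.22 and pDC-like 0.41. With cells over 10% haemoglobin left out, list medians were B-cell activation and antibody secretion in B-like -0.53, type I interferon response in B-like -0.15, cell cycle in DC-like -0.0825, complement and phagocytosis in DC-like -0.24, dynein adaptors and Rab6 transport in DC-like 0.24, type I interferon response in DC-like -0.22 and type I interferon response in pDC-like -0.39. With cells over 10% haemoglobin left out, the reversed gene log2 ratio of Prxl2a in pDC-like cells was -0.92. With doublets kept, the share log2 ratio of monocyte-macrophage-like cells was 0.26. With red-cell clusters left out of the total, share log2 ratios were T-like 0.18, NK-ILC1-like 0.0554, B-like 1.42, neutrophil-like -1.16, monocyte-macrophage-like 0.37 and DC-like 0.42. With estimated free RNA subtracted, list medians were B-cell activation and antibody secretion in neutrophil-like 0.19 and cell cycle in pDC-like -0.54. With estimated free RNA subtracted, reversed gene log2 ratios were Wfdc21 in B-like 0.22, AW112010 in erythroid-like 0.0683 and Cd52 in erythroid-like 2.304. With genes centred within library, share log2 ratios were T-like 0.0751, B-like 1.05, monocyte-macrophage-like 1.12 and DC-like 0.60. The 1.12 leaves out an unnamed cluster of 929 WT and 71 KO cells that met classical monocyte markers. With a minimum count of 100, list medians were helper T cytokines and regulators in T-like -0.0452, cell cycle in NK-ILC1-like -0.44 and MHC class II presentation in DC-like -0.35. With no minimum count, list medians were helper T cytokines and regulators in T-like 0.11, T-cell exhaustion and checkpoint in neutrophil-like 0.26, endoplasmic reticulum stress in DC-like -0.30 and T-cell exhaustion and checkpoint in pDC-like 0.13. With the stricter cell filter, share log2 ratios were T-like 0.0476, NK-ILC1-like -0.27, neutrophil-like -1.69 and progenitor-like -4.28. With the stricter cell filter, list medians were B-cell activation and antibody secretion in B-like -0.63 and MHC class II presentation in DC-like -0.33. With cells thinned to 1000 UMIs, share log2 ratios were T-like -0.0762, neutrophil-like -2.11 and monocyte-macrophage-like 0.35. With cells thinned to 1000 UMIs, list medians were helper T cytokines and regulators in T-like -0.0839, cell cycle in NK-ILC1-like -0.36, oxidative phosphorylation in NK-ILC1-like -0.26, endoplasmic reticulum stress in B-like -0.24, type I interferon response in B-like -0.27, complement and phagocytosis in monocyte-macrophage-like -0.44, lipid-associated macrophage in monocyte-macrophage-like -0.51, B-cell activation and antibody secretion in neutrophil-like -0.21, T-cell exhaustion and checkpoint in neutrophil-like 0.47, immediate early and dissociation stress in neutrophil-like 0.38, MHC class II presentation in DC-like -0.27, complement and phagocytosis in DC-like -0.00468, endoplasmic reticulum stress in DC-like -0.18, glycolysis and hypoxia in DC-like -0.32, endoplasmic reticulum stress in pDC-like -0.55 and type I interferon response in pDC-like -0.67.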

Other observations

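The test on T-cell receptor genes reported here was chosen after the result was seen. Genes of dynein adaptors and Rab6 transport, the pathway in which BICD2 acts, did not stand apart in any of the 7 leukocyte lineages, with medians from -0.12 in B-like to 0.08 in DC-like cells, where it did stand apart higher, at 0.24, with cells over 10% haemoglobin left out. In T-like cells they went both ways: the dynactin subunit Dctn3 was 1.99-fold lower and the vesicle GTPase Rab6b 1.38-fold higher in KO. Heat shock chaperones likewise did not stand apart in any of the 7, with medians from -0.31 in T-like to 0.08 in DC-like cells. Genes of endoplasmic reticulum stress stood apart lower in 4 lineages: T-like (median -0.48, percentile 0.54), B-like (-0.34, percentile 0.12), DC-like (-0.33, percentile 1.67) and pDC-like cells (-0.66, percentile 0.04). They no longer stood apart when cells were thinned in B-like (-0.24), DC-like (-0.18) and pDC-like cells (-0.55), nor in DC-like cells with no minimum count (-0.30). In T-like cells 11 of 14 were lower, with the chaperones Hspa5 and Calr 1.54-fold and 1.74-fold lower and the stress factor Ddit3 1.76-fold higher.

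Genes of alternative macrophage activation and repair were lower in 9 of 13 cases in monocyte-macrophage-like cells (median -0.49). Chil3, a chitinase-like protein, Hmox1, which degrades haem, and Arg1, the arginase of repair macrophages, were 1.899-fold, 1.96-fold and 2.75-fold lower in KO, and the scavenger receptors Cd163 and Marco 4.44-fold and 39.5-fold. Cd163 and Marco also mark Kupffer cells and had UMIs in few cells of WT and KO (Cd163 in 18 and 7, Marco in 35 and 2), as had the Kupffer-cell markers Clec4f (38 and 3) and Vsig4 (33 and 3), while C1qa, which Kupffer cells share with other macrophages, had UMIs in 164 and 163. Complement genes were mixed there, with C1qb, a part of the C1q complex, 1.35-fold and properdin (Cfp) 1.56-fold higher, and C3 and the antibody receptor Fcgr1 1.87-fold and 2.41-fold lower. In all T-like cells Trav11 and Trav11d gave 3.69% of T-cell receptor alpha variable UMIs in WT (15 of 407) and 32.3% in KO (43 of 133).

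As a check that the mice of both libraries were alike in sex and substrain, Xist, expressed from the inactive X chromosome, had 4 UMIs in WT and 0 of 41674206 in KO, which allows up to 0.07199 CPM, and the Y-linked Ddx3y 4349 and 3250 UMIs. Nnt, which some C57BL/6 substrains lack in part, was at 3.07 and 2.93 CPM. Barcodes with more than 50% haemoglobin UMIs numbered 3687 in WT (16.6%) and 12021 in KO (44.5%).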
